A study of Mus musculus with 4 samples.

How the data were processed

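Chromatin accessibility was measured by Omni-ATAC-seq, an assay in which Tn5 transposase cuts and tags open DNA, in γδ T cells sorted from pooled fetal mouse thymi. Per the labels, each library started from sorted cells (15 to 17, in units of 1000) of embryonic day 17 to 18 fetuses on a C57BL/6 background after 5 generations of backcrossing, and was amplified for 9 to 11 PCR cycles. The labels gave 2 libraries of Maf+/+ Il7r-Cre fetuses (WT) and 2 of Maf fl/fl Il7r-Cre fetuses (KO), with the replicate numbers 1 and 2 in each genotype. The labels did not say whether the 2 libraries of a genotype came from separate litters or pools, so the spread between them may be technical. The p-values of gene lists and of gene-end shares come from resampled genes or from counts of regions, and do not measure the spread between libraries.

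The submitters' processing notes name Trim Galore, cutadapt, Bowtie2 2.3.4.1, Picard, bedtools, deepTools 3.1.2 and MACS2 2.1.1, and the builds GRCm38 and mm10, without the role of each. Whether reads were shifted for the Tn5 cut, how duplicates were treated and which peak settings were chosen are not given in the sources used here. The deposited data were 1 peak list per library in the narrowPeak layout, so peaks had been called library by library and not on pooled reads. In the deposited lists, each peak carried a whole-number score, which was 10 times the −log10 q without its decimals for nearly every peak. The authors' lists also gave a fold enrichment, the ratio of the summit to the local background of the same library. The deposited −log10 p and −log10 q of each summit were likewise computed within the library, and every list ended at a q of 0.1. These are the authors' own values and were used only to describe, rank or filter peaks within a list. Read totals were not analysed here, so the depth of a library was described by its number of peaks and by its background. The background pileup was computed from the deposited fold and −log10 p of the peaks that shared the lowest background, under the Poisson model of the peak caller, and described depth only.

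Peaks on chromosomes 1 to 19 and X entered the comparisons, and each entry of a list counted as 1 peak. Peaks of the 4 libraries that overlapped by 1 bp or more were merged into regions, and a region was called in a library when a peak of that library overlapped it. WT-only regions were called in both WT libraries and neither KO library, and KO-only regions the reverse. The regions called in 1 WT and 1 KO library alone gave the background of mixed pairs. Tall regions were those in the top 25% of peaks by −log10 q in both libraries that called them. Pattern ratios divided the product of the counts of 1 way of pairing the libraries by the product of another, which cancels the number of peaks per library when calls are independent. Their 95% intervals came from 1000 bootstrap samples of 10 Mb blocks of the genome and do not cover the spread between libraries. With 2 libraries against 2 there are 3 ways to pair the libraries, so the smallest exact p for a split of the libraries was 0.333. Similarity of peak sets was the Jaccard index, shared base pairs over base pairs covered by either library.

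Regions were assigned to the nearest gene body within 100 kb, using a RefSeq gene table of GRCm38, the build of the peak lists. The table used here has gene starts and ends without strand or exons, so gene bodies replaced the planned transcription start sites, a promoter was replaced by 1 kb around either gene end, and exon or intron positions are not given. Positions are 1-based. The planned motif analysis was not run because no genome sequence was used here. Regions were merged by code with the planned rule of any overlap, in place of bedtools.

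For each of 13 gene lists, WT-only minus KO-only regions were compared with 100000 sets of genes matched on the number of regions called in at least 2 libraries (consensus regions), in a 2-sided permutation test with Benjamini-Hochberg adjustment over the lists. The lists were the type 17 program, the type 1 program, T cell receptor signal response, the immature thymocyte and TCF1 module, published c-Maf target genes, MAF, CNC and AP-1 factors, T cell identity, conventional αβ thymocyte, B cell, myeloid, erythroid, thymic epithelium and stroma, and housekeeping promoters. All 239 list entries, 227 distinct genes, matched the gene table. The targeted gene, Maf, stands in the type 17 list and in the list of MAF, CNC and AP-1 factors. In the type 17 list 7 of 28 genes also stood in another list, in the immature list 4 of 24 and in the c-Maf target list 5 of 20. Gene-end shares were compared by Fisher's exact test, with exact Clopper-Pearson 95% intervals, which cover counting error only. Tested on simulated data over 17351 genes, the list test passed an unadjusted p of 0.05 in 6.5% of unchanged lists of 28 genes. It did so in 33.0% with a 2-fold WT-only rate and in 95.5% with a 4-fold rate. The simulated calls were independent, at a genome-wide rate, and the lists were random genes. Clustering of regions along the genome was not simulated, so these shares need not hold for the lists tested here.

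Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named were Maf, the 10 WT-only and 10 KO-only regions of highest rank, up to 4 genes per list with a WT-only or KO-only region, and Il17a, Il17f, Il23r, Blk, Sox13, Tcf7, Tbx21, Ifng and Cd27 in any case. A region's rank was the lower of its within-library percentiles by −log10 q. Some genes that the rule names are not reported here. Genes outside this rule are marked as chosen after their values were seen. The alternatives were a −log10 q of at least 5 for presence, equal numbers of peaks, autosomes alone, coverage of at least 0.5 of a region, each library left out, assignment within 20 kb, gene ends widened to 2.5 kb, the top 10% for tall regions, Fisher's exact test over regions, and a Cochran-Mantel-Haenszel test with the replicate number as block. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.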

Results

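Accessible chromatin was mapped in immature γδ thymocytes of the fetal mouse, sorted as CD24-positive cells with low CD45RB, a stage of the γδ T cells that go on to make IL-17. The design asked how loss of c-Maf, a basic leucine zipper transcription factor, alters accessibility in these cells. In the KO fetuses, Cre driven by Il7r deletes the floxed Maf gene in lymphoid precursors. The WT libraries held 102718 and 132179 peaks on the autosomes and X, and the KO libraries 130935 and 120141. The mean was 117448 ± 20832 peaks in WT and 125538 ± 7633 in KO (SD, n = 2 each), a difference of means smaller than the gap between the 2 libraries of either genotype. Peaks covered 20.6 and 29.5 Mb in WT 1 and WT 2, and 25.8 and 26.8 Mb in KO 1 and KO 2. Background pileup was 1.57 and 1.38 in the WT libraries and 0.877 and 0.758 in the KO libraries, so the genotypes did not overlap in this measure.

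The targeted gene itself separated the genotypes. Maf lies on chromosome 8 from 115703253 to 115706894 (GRCm38). Both WT libraries had a peak inside the gene at 115705837 to 115705990 and a wider one at 115706902 to 115707609, 8 bp from the gene, and neither KO library had a peak at either position. Their −log10 q was 15.0 and 16.0 in WT 1, and 15.9 and 23.8 in WT 2. From 115705095 to 115708471, a stretch of 3377 bp across the gene boundary at 115706894, no KO peak was called. In it 3 peaks of WT 1 and 4 of WT 2 began, including the tallest of the locus (−log10 q of 89.9 and 140.8). The labels do not give the floxed interval, so KO peaks missing here cannot be told apart from deleted DNA. Just outside this stretch the KO libraries had peaks where WT had none, at 115709069 to 115709732 in both. One weak peak inside the gene, at 115704898 to 115705094, was called in both KO libraries and in WT 1, with a −log10 q of 3.17, 3.06 and 1.02. The merged region from 115707722 to 115708810 counted as called in all 4 libraries, although the KO peaks in it began at 115708472 or later and the WT peaks ended by 115708481. Farther out, WT-only regions lay 27.1 kb and 38.9 kb from Maf.

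The locus of Il17a and Il17f held several regions called in WT alone. Il17a and Il17f, which encode the IL-17 cytokines, lie side by side on chromosome 1, and 4 of their 10 consensus regions were WT-only (40%, exact 95% interval 12.2% to 73.8%) while 0 were KO-only. Over the genome, 2.89% of consensus regions were WT-only and 4.34% KO-only. The regions assigned to Il17a stood at 20685778 to 20686183, 20715350 to 20715629 and 20725605 to 20726152, that is 44.7, 15.3 and 4.75 kb from the gene. The farthest of them was the tallest, with a −log10 q of 37.0 in WT 1 and 52.5 in WT 2, and was among the 10 highest ranked WT-only regions of the genome. The WT-only region assigned to Il17f was at 20759737 to 20760053. Of the 10 consensus regions 5 were called in all 4 libraries, so the locus was not closed throughout. Those between the genes included 20740397 to 20740906 and 20743862 to 20744282. The smallest summit called at the background pileup was 4.46 and 4.35 times that background in WT 1 and WT 2. In KO 1 and KO 2 it was 5.70 and 6.60 times, so a missing KO call need not mean closed chromatin. Having at least 3 WT-only and 0 KO-only regions, as Il17a did, was found in 8 of the 4849 genes with 5 to 10 consensus regions (0.165%), a comparison chosen after the values were seen.

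**Figure D1:**
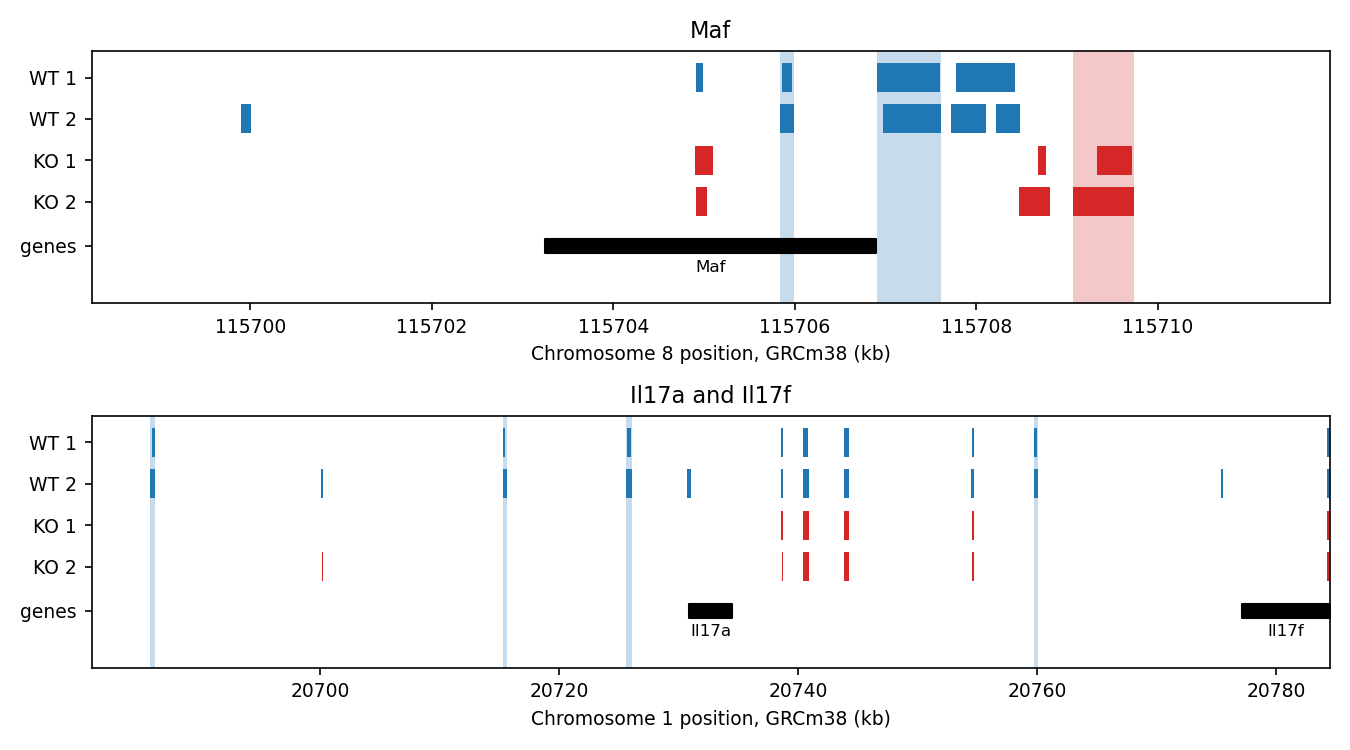
Maps of called peaks at Maf and at Il17a and Il17f, with position in kb (GRCm38) on the horizontal axis and 1 line per library (blue WT, red KO). Pale bands mark WT-only regions (blue) and the KO-only region (red), and black bars are genes. At Maf the KO libraries have no peak from 115705095 to 115708471.

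Other genes of the type 17 program followed in part. Il23r, the receptor subunit for IL-23, had 2 WT-only regions within the gene on chromosome 6, at 67431800 to 67431989 and 67434514 to 67434672. The first had a −log10 q of 10.3 and 12.6 in WT 1 and WT 2, the second 2.91 and 3.55. Sox13, a factor of γδ lineage specification, had 1 at 133404030 to 133404202 on chromosome 1. Il1r1 had 3 WT-only regions, and Il7r, Ccr2, Cd163l1, Serpinb1a and Actn2 had 1 each, with 0 KO-only regions in all of these. Blk, a kinase of γδ T cells that make IL-17, had 0 of either kind among 17 consensus regions. Zbtb16, which encodes PLZF, a factor of innate-like T cells, went the other way with 5 KO-only and 0 WT-only regions among 49. So did Ccr6, Sox4, Etv5 and Tmem176b, with 1 KO-only and 0 WT-only regions each. Rora had 1 WT-only and 2 KO-only regions, and Ramp1 had 1 of each kind. The 5 KO-only regions of Zbtb16 had a −log10 q of 1.69 to 3.11 in KO 1 and 3.18 to 6.76 in KO 2. With a −log10 q of at least 5 for presence, the list without Maf had 9 WT-only and 0 KO-only regions. None of the KO-only calls at the genes named here thus met that stricter rule. Il1r1, Zbtb16 and the genes listed with them were chosen after their values were seen.

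Of the 28 type 17 genes, 11 had WT-only regions alone, 5 had KO-only regions alone, 3 had both and 9 had neither. The list held 22 WT-only and 13 KO-only regions, of which the deleted gene itself, Maf, gave 4 and 1. This was 13.6 more in favour of WT than the mean of matched gene sets (95% range of the sets −16 to 6 around −4.63, observed 9), with p = 0.0194 in the permutation test and an adjusted p of 0.252 over the 13 lists. The list therefore missed the adjusted threshold as planned. It passed when presence needed a −log10 q of at least 5, which left 12 WT-only regions and 1 KO-only region (adjusted permutation p = 0.00208), and without WT 1 (adjusted permutation p = 0.0166). With Maf left out of the list, which was tried after seeing the data, 18 WT-only and 12 KO-only regions remained (excess 10.4, permutation p = 0.0715, adjusted p = 0.660). Without Maf the list still passed at a −log10 q of at least 5, with 9 WT-only and 0 KO-only regions (adjusted permutation p = 0.00897). Without both Maf and WT 1 the excess was 25.5. Over the alternatives without a block on replicate number the adjusted p ran from 0.00208 to 0.660.

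No other list passed the adjusted threshold as planned. The type 1 program, the genes of interferon-γ-producing cells, had 9 WT-only and 11 KO-only regions over 25 genes (adjusted permutation p = 0.992). Within it, Ifng and Cd27 had 0 of either kind among 27 and 9 consensus regions. Tbx21 had 1 WT-only region, with a −log10 q of 2.29 and 2.48 in WT 1 and WT 2. Eomes had 2 WT-only and 5 KO-only regions, Stat4 had 3 and 2, and Runx3 had 1 and 2. Cxcr3 had 1 KO-only region. The immature thymocyte and TCF1 module had 18 WT-only and 33 KO-only regions over 24 genes, an excess of −8.95 (adjusted permutation p = 0.576). Its direction turned with the library left out, as the excess was −31.5 without KO 1 (adjusted permutation p = 0.0811, in a range of 0.0811 to 1.00 over the alternatives), 10.7 without WT 2, 1.20 without WT 1 and 0.505 without KO 2. Tcf7, which encodes TCF1, had 0 of either kind among 22 consensus regions, of which 17 were called in all 4 libraries. Bcl11b had 4 WT-only regions and 1 KO-only region, Ets1 had 1 and 3, and Myb had 1 and 1. At Bcl11b the lower within-library percentiles were 5.42 to 16.0 for WT-only regions and 40.8 for the KO-only one. The published c-Maf target genes had 13 WT-only and 11 KO-only regions, an excess of 5.27 (adjusted permutation p = 0.628). Of its 20 genes, 6 had WT-only regions alone, 3 had KO-only regions alone, 2 had both and 9 had neither. Il17a, which also stands in the type 17 list, had 3 WT-only regions, Tigit had 2 and Ahr had 1. Sox5 had 2 WT-only regions and 7 of the 11 KO-only ones, and Ccr6, Prdm1 and Pdcd1 had 1 KO-only region each. Sox5, Ccr6, Prdm1 and Pdcd1 were chosen after their values were seen. Without WT 1, where WT-only regions rested on WT 2 alone, the c-Maf target list had 67 WT-only and 11 KO-only regions (excess 26.4). With equal numbers of peaks it had 18 and 6 (excess 10.7, permutation p = 0.0220, adjusted p = 0.0955), and within 20 kb 9 and 11 (excess 0.214, adjusted permutation p = 1.00). The MAF, CNC and AP-1 factors had 11 and 8, an excess of 5.90 (adjusted permutation p = 0.576), with the deleted Maf included. Without Maf the list had 7 and 7 (adjusted permutation p = 0.951), and without WT 1 its excess turned to −8.02. Bach1 had 3 WT-only regions, Fos had 1, and Jun had 1 WT-only and 2 KO-only regions. Genes induced by T cell receptor signals had 5 WT-only and 8 KO-only regions (adjusted permutation p = 0.992). Nr4a3 had 1 WT-only region, and Egr1, Cd69 and Myc had 1, 1 and 2 KO-only regions.

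**Figure D2:**
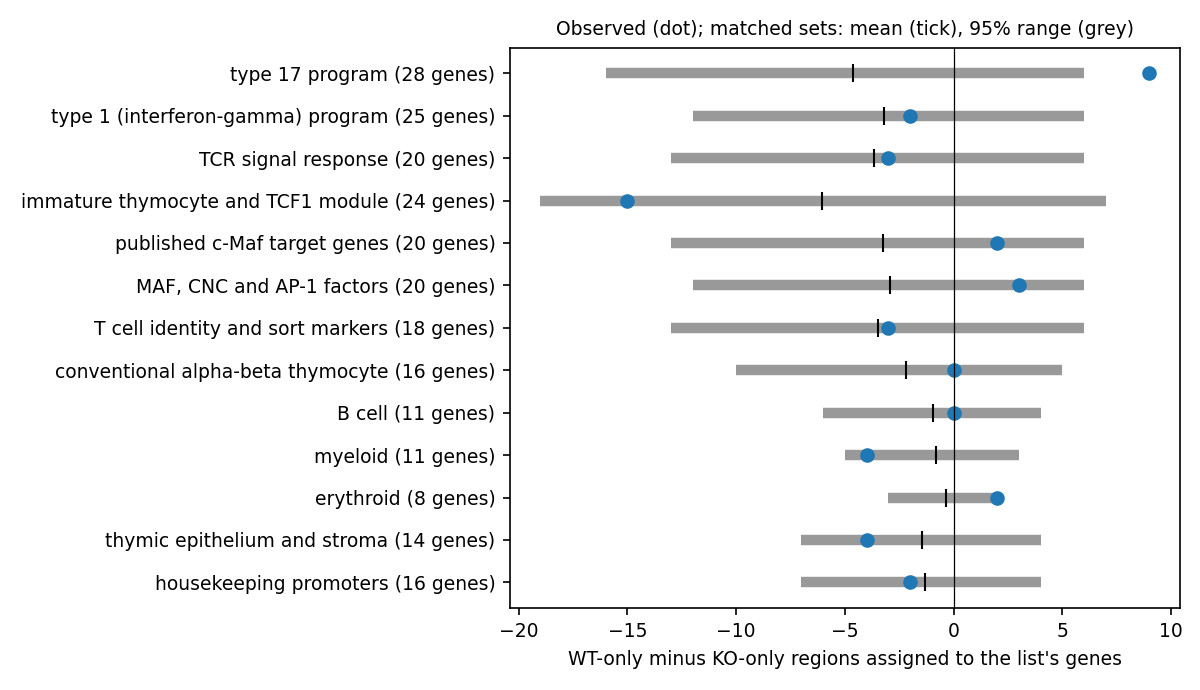
WT-only minus KO-only regions assigned to the genes of each list (horizontal axis, number of regions). Dots are observed values, ticks the mean and grey bars the 95% range of matched gene sets. The type 17 program, with the deleted Maf included, stands at 9, above its range of −16 to 6.

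Genes of other cells that a thymic sort could carry were tested in the same way, and none of their lists passed the adjusted threshold. T cell identity genes had a peak within 1 kb of a gene end for 18 of 18 genes in every library. Their list held 5 WT-only and 8 KO-only regions (adjusted permutation p = 1.00), with a WT-only region at Cd2, 1 of each kind at Thy1 and 3 KO-only regions at Ptprc. The lower within-library percentiles were 15.6 at Cd2, 40.9 (WT-only) and 8.21 (KO-only) at Thy1, and 0.439 to 15.9 at Ptprc. Conventional αβ thymocyte genes had 3 of each kind (adjusted permutation p = 0.951), at Cd8b1 (WT-only), Themis and Trbc2 (KO-only) among others, and 11 of 16 gene ends with a peak in every library. B cell genes had 2 of each kind (adjusted permutation p = 0.992), both WT-only ones at Ebf1 and the KO-only ones at Cd22 and Pax5. Myeloid genes had 0 WT-only and 4 KO-only regions, at Mpo, Itgam, Spi1 and Csf3r (excess −3.19, adjusted permutation p = 0.576), and gene ends with a peak numbered 5 in WT 1 and 7 in WT 2, KO 1 and KO 2. The myeloid list had 0 and 13 without KO 1 (excess −8.79) and 0 and 6 with at least 0.5 of a region covered (excess −4.99, permutation p = 0.05001, adjusted p = 0.325). Its excess or log2 odds ratio was below 0 in all 18 alternatives. Those that left Maf out only repeated others, since Maf is not in this list. Erythroid genes had 2 WT-only regions, both at Gata1 on X (adjusted permutation p = 0.576). With autosomes alone, or at a −log10 q of at least 5, the erythroid list had 0 of either kind. Erythroid gene ends with a peak numbered 4 in WT 1, 5 in WT 2 and 6 in both KO libraries. Stromal genes had 5 WT-only and 9 KO-only regions among 110 consensus regions (adjusted permutation p = 0.708). The endothelial genes Cdh5 and Pecam1 held 0 and 4 WT-only and 3 and 2 KO-only regions, and the collagen genes Col1a1 and Col1a2 had 1 KO-only region each. Housekeeping genes had 2 WT-only regions, at Actb and Eef1a1, and 4 KO-only regions, of which 2 were at Polr2a and 1 at Hprt (adjusted permutation p = 0.992).

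Across the genome, 171490 merged regions were found, of which 78650 (45.9%) were called in all 4 libraries. WT-only regions numbered 3542 and KO-only regions 5311. The median width was 143 bp for KO-only regions and 274 bp for regions called in all 4 libraries, with WT-only regions in between. Mixed pairs shared 1384 regions (WT 1 and KO 1), 5673 (WT 2 and KO 2), 965 (WT 1 and KO 2) and 5951 (WT 2 and KO 1). WT-only and KO-only regions were thus each fewer than those of 2 mixed pairs, both of which included WT 2. Summed over both pairs, the genotype split gave 8853 regions against 7057 and 6916 for the other splits, the highest of 3 (exact p = 0.333, the smallest this design allows). The pattern ratio of genotype over crossed pairs was 3.28 (95% interval 3.03 to 3.56), and that of replicate number over crossed pairs was 1.37 (1.248 to 1.498). When the top 102718 peaks of each library were kept, WT-only and KO-only regions numbered 4244 and 4058 and mixed pairs 1757 to 3068. Counts rose when 1 library was left out, since fewer lists then had to meet the rule. WT-only and KO-only regions were 20412 and 6866 without WT 1, 9031 and 18303 without WT 2, 6711 and 14625 without KO 1, and 6857 and 22621 without KO 2.

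**Figure D3:**
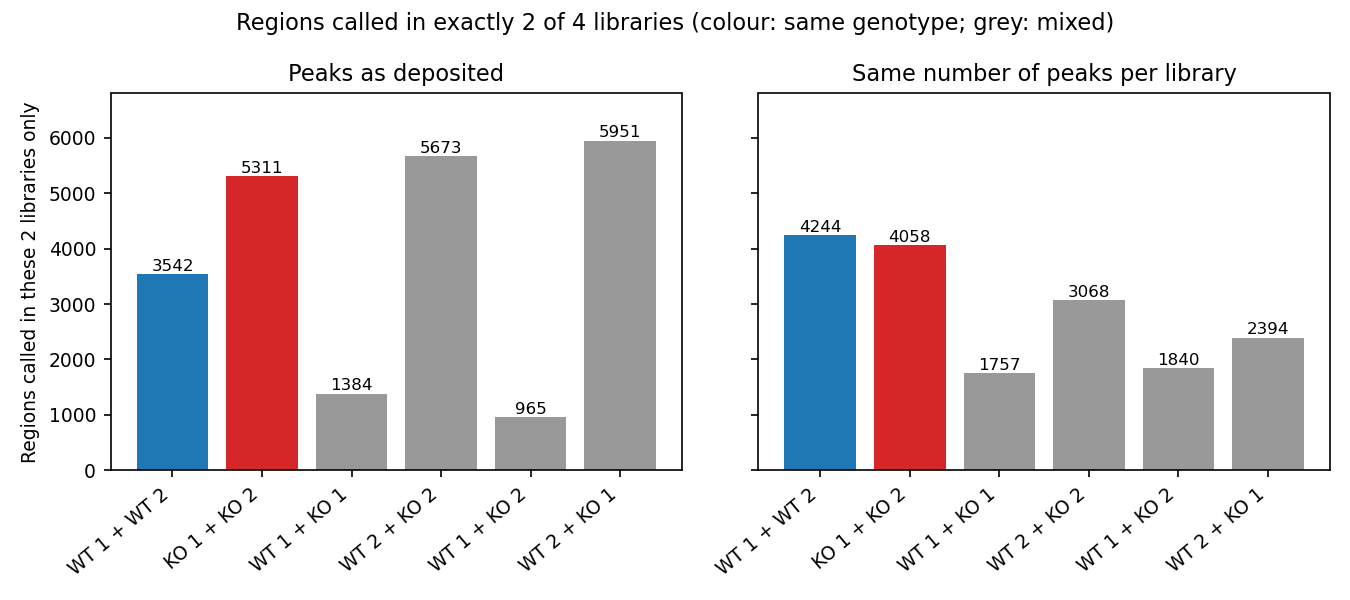
Number of regions called in exactly 2 of the 4 libraries, for each pair of libraries (vertical axis from 0), with peaks as deposited on the left and 102718 peaks per library on the right. Coloured bars are pairs of 1 genotype and grey bars mixed pairs. With equal numbers of peaks, the WT pair (4244) and the KO pair (4058) lie above the mixed pairs (1757 to 3068).

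Tall genotype-specific regions, those in the top 25% of peaks in both libraries of a genotype, numbered 24 WT-only and 2 KO-only. With at least 0.5 of a region covered they numbered 87 and 30, and in the top 10% there were 0 of either kind, against 21 shared by WT 1 and KO 1 alone. The highest ranked WT-only region was within Mapk14, which encodes a p38 kinase, at 28716196 to 28716461 on chromosome 17 (−log10 q of 58.1 and 142.0). It was followed by regions within Hc (complement component 5), Synj2, Ttll11, Cul5 and Ube2cbp, the Il17a region described above, a region 21 bp from Uggt2, and regions within Eif3m and Aopep. At all of these genes except Hc and Aopep, 0 regions were KO-only. The tall KO-only regions were within Lrrc2, at 110982561 to 110982940 on chromosome 9 (−log10 q of 43.3 and 70.2), and within Arhgap26, at 39185655 to 39186056 on chromosome 18 (50.9 and 46.7). Below these ranked regions at Ttll10, Cavin4, Clec3a, Irf2, Agbl4, Bsn and Tmtc2, with lower within-library percentiles of 58.3 to 69.3. WT-only regions were assigned to some of these genes too, 3 to Arhgap26, 2 to Irf2 and 1 each to Ttll10 and Bsn, and 0 to Lrrc2, Cavin4, Clec3a, Agbl4 and Tmtc2. In mixed pairs, 32 tall regions were shared by WT 1 and KO 1, and 1 by WT 2 and KO 1. All 32 were 64 to 78 bp wide, and with regions over 100 bp alone the counts were 24 WT-only, 2 KO-only, 0 for both replicate-number pairs and 1 for the crossed pairs. Without WT 1 there were 135 tall WT-only regions, without KO 1 48 and without KO 2 37, and tall KO-only regions numbered 10 without WT 2 and 10 without KO 2.

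As whole sets, the peak lists of 1 genotype were hardly more alike than lists of different genotypes. The Jaccard index was 0.590 for the WT pair, 0.643 for the KO pair and 0.586 to 0.648 for mixed pairs. Pairs of 1 genotype lay 0.00609 above mixed pairs on average, against 0.00654 for pairs of 1 replicate number (exact p = 0.667 over the 3 splits). The order of the splits turned with the measure. The same differences were 0.0149 for genotype and 0.0026 for replicate number with equal numbers of peaks, 0.0109 and −0.0055 by shared regions, and 0.0041 and 0.0158 for peaks with a −log10 q of at least 5. The difference was −0.0315 without KO 1, −0.0101 without KO 2 and 0.0531 without WT 2.

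WT-only regions lay near gene ends somewhat more often than KO-only regions. Within 1 kb of a gene end were 10.1% of WT-only regions (95% interval 9.11% to 11.1%), 7.34% of KO-only regions (6.66% to 8.08%) and 20.6% of regions called in all 4 libraries. The difference of 2.74 percentage points had p = 6.97e-06 in Fisher's exact test over regions, which are not independent replicates. The share differed between the WT libraries themselves, at 19.9% and 16.4% of peaks, and was 17.0% and 17.1% in the KO libraries. Without WT 1 the difference was −0.0323 points (Fisher's exact p = 0.939), and with a −log10 q of at least 5 it was −0.330 points (Fisher's exact p = 0.785).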

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

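All tests of explanations in this part were chosen after the result was seen, except that of passenger DNA outside chromosome 8 with peaks as called.

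The Y chromosome, left out of the comparisons, had 134 peaks in KO 1 and 95 in KO 2, above the 82 and 93 of the WT libraries. This is 0.102% and 0.0789% of all peaks in the KO libraries, and 0.0795% and 0.0702% in WT.

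Summed over both pairs, regions shared by the libraries of 1 genotype were in excess of those of the other splits. Pair by pair this did not hold for peaks as called. WT 2 with KO 2 (5673) and WT 2 with KO 1 (5951) shared more than the WT pair (3542) or the KO pair (5311). In these 4 libraries the number of peaks was not the whole cause, since with equal numbers of peaks the WT pair (4244) and the KO pair (4058) shared more regions than every mixed pair (1757 to 3068), a ratio of genotype over crossed pairs of 3.91, although 3 splits allow no exact p below 0.333. Replicate number as a batch had a ratio over crossed pairs of 1.37 as called, above 1 but below the 3.28 of genotype over crossed pairs. The ratio of genotype over replicate number was 2.40. A difference in depth or background cannot be told apart from genotype, because the mean background pileup was 1.80 times as high in WT and the genotypes did not overlap. Tall regions numbered 26 for genotype, 32 for replicate number and 1 for crossed pairs, and 26, 0 and 1 with regions over 100 bp alone, but 26 of 8853 genotype-specific regions do not settle this for the others. Loss of c-Maf remains a biological explanation that these tables leave open.

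With all 4 libraries, WT-only regions at type 17 genes outnumbered KO-only ones (22 and 13), as they did without WT 1 (93 and 22). They were fewer than KO-only ones without WT 2 (42 and 50), KO 1 (37 and 39) or KO 2 (37 and 52), where KO-only regions also prevailed over the genome. Passenger DNA carried along with the targeted Maf allele could not place WT-only regions on other chromosomes. On chromosome 8, Maf is the only gene of the list and gave 4 of the 22 WT-only regions. At a −log10 q of at least 5 the excess outside chromosome 8 was 9.09 (9 WT-only and 0 KO-only regions, permutation p = 0.00069), above the 95% range of matched sets, which argues against passenger DNA around Maf as the whole cause there. With peaks as called it was 10.4 (18 and 12, permutation p = 0.0715), inside that range, so whether the list as called stands apart without Maf stays open, although over 10 settings the excess was above 0 in each and above the range in 6. A KO sort with fewer type 17 cells and more cells of other kinds cannot be told apart, as the lists of other cells went both ways. Together, 84 genes of 6 lists of other cells or programs gave an excess of −0.153 (20 WT-only and 29 KO-only regions, permutation p = 1.00). By list it ran from −3.19 for myeloid genes to 2.36 for erythroid genes. The myeloid value was below 0 in all 18 alternatives, of which those without Maf repeated others. The erythroid value rested on 2 regions at Gata1 and was 0.291 with autosomes alone. Segments elsewhere that 5 generations of backcrossing may have left were not tested, and direct control of these regions by c-Maf and an altered mix of cells of the γδ lineage both remain biological hypotheses.

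Tall regions called in both replicate 1 libraries and neither replicate 2 library were all narrow. Of the 32, 100% were 100 bp wide or less, against 0% of the tall WT-only regions, which were 186 to 751 bp wide. The narrowest peak of any kind was 64 bp in both replicate 1 libraries and 79 and 84 bp in the replicate 2 libraries. This is consistent with stacks of reads at single positions in the replicate 1 libraries, and the design gives no biological explanation that was tested.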

How the results depend on the processing

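Chosen after seeing the data were the tests with regions over 100 bp, with the nearest gene end, with Maf left out of the lists, with each library left out for similarity, and of type 17 genes outside chromosome 8 under settings other than peaks as called. The other alternatives were planned. The planned motif alternatives were not run, since no sequence was used here. Where values moved, the cause was not tested, except that stricter rules or fewer libraries change the number of regions by construction. Genotype-specific regions ranked low within their libraries, with a mean percentile of 25.7 for WT-only and 21.7 for KO-only against 65.2 for regions called in all 4 libraries, and whether depth limited their calls was not tested.

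A −log10 q of at least 5 left 918 WT-only and 1068 KO-only regions. With each library left out in turn, WT-only regions ran from 6711 to 20412 and KO-only regions from 6866 to 22621. Tall regions numbered 87 WT-only and 30 KO-only with at least 0.5 of a region covered, and 0 and 0 in the top 10%. With each library left out, tall WT-only regions ran from 30 to 135 and KO-only from 2 to 10. The similarity difference ran from −0.0315 (without KO 1) to 0.0531 (without WT 2), and was −0.0101 without KO 2. Of the named regions, 34 of 58 WT-only and 26 of 56 KO-only kept their call at a −log10 q of at least 5, and 36 KO-only ones with equal numbers of peaks.

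The type 17 excess kept its sign in all 18 alternatives. It passed the adjusted threshold with a −log10 q of at least 5 (11.1, with 1 list past the threshold). Without WT 1, where WT-only regions rested on WT 2 alone, it was 30.3. With Maf left out of the list it passed at a −log10 q of at least 5 (9.09, with 1 list past the threshold), and it was 25.5 without WT 1. Outside chromosome 8 the excess ran from 8.96 (regions over 100 bp) to 25.5 (without WT 1). With each library left out the whole list ran from 19.1 to 30.3. The c-Maf target excess without WT 1 was 26.4. The myeloid excess ran from −8.79 (without KO 1) to −2.34 (without WT 1) with each library left out. The difference in gene-end share reversed to −0.330 points at a −log10 q of at least 5, and ran from −0.0323 to 4.44 points with each library left out.

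The replicate numbers give only 2 pairs and no label says what they share, although the narrowest peaks were alike within a number (64 and 64 bp for replicate 1, 79 and 84 bp for replicate 2). With the replicate block, type 17 genes (log2 odds ratio 0.63) and c-Maf targets (0.75) passed, so 2 lists were past the threshold in a test that counts regions as independent. With Maf left out of the lists, type 17 genes still passed under the block (0.63), again with 2 lists past the threshold, and MAF factors turned to −0.0547. Signs turned, without passing the threshold, for T cell identity (−0.19), erythroid (−0.27) and housekeeping genes (0.36).

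Lists that were not past the threshold also changed sign elsewhere. At a −log10 q of at least 5 the excess was −1.78 for type 1, −0.822 for T cell receptor response, −0.891 for αβ thymocyte and 2.09 for housekeeping genes. With equal numbers of peaks it was −0.267 for B cell and 4.64 for housekeeping genes, with autosomes alone 0.207 for housekeeping genes, and with at least 0.5 of a region covered 0.887 for stroma. Within 20 kb it was −0.674 for T cell identity and 1.98 for stroma, and by the nearest gene end −0.876 for T cell receptor response and −0.00974 for T cell identity. Fisher's exact test over regions gave a log2 odds ratio of −0.14 for T cell receptor response and −0.14 for T cell identity. With libraries left out, the excess ran from −4.49 to 11.5 for T cell receptor response, −31.5 to 10.7 for the immature module (1.20 without WT 1), −12.9 (Maf left out) or −8.02 to 11.9 for MAF factors, −16.3 to 7.63 for T cell identity, −3.83 to 9.49 for αβ thymocyte, −1.81 to 3.14 for erythroid, −0.792 to 8.08 for B cell and 0.419 to 2.67 for housekeeping genes.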

Other observations

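The passenger DNA test below was written before its result was seen, and every other comparison in this part was chosen after.

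Further genes and windows held many genotype-specific regions. On chromosome 5, the window from 15000001 to 16000000 had 30 WT-only regions among 80 consensus regions and 0 KO-only ones, of which Speer4d held 10 and Speer4c 7, members of a multicopy gene family. In the opposite direction, the window from 11000001 to 12000000 of the same chromosome had 17 KO-only regions among 51 and 0 WT-only, 7 of them at the predicted gene Gm5861. Among list members, Runx1, a regulator of thymocyte development, had 3 WT-only and 7 KO-only regions, and Kit, the stem cell factor receptor of early progenitors, had 1 and 4. At Il10, a known c-Maf target, 1 region was WT-only. Genes with at least 3 WT-only and 0 KO-only regions numbered 45 of 17351, and those with at least 3 KO-only and 0 WT-only regions 94. For Zbtb16, 5 or more KO-only regions with 0 WT-only were found in 3 of 147 genes with 40 to 60 consensus regions. All 5 regions at Zbtb16 fell short of a −log10 q of 5 in KO 1.

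A hypothesis of passenger DNA was tested on the flanks of Maf itself. In the 5 Mb on either side of Maf, 52 of 815 consensus regions were KO-only (6.38%, against a median of 4.41% over 240 windows of 10 Mb) and 24 were WT-only (2.94%, against 2.80%). The KO-only share stood at percentile 92.1 of the windows and the WT-only share at percentile 55.0, so passenger DNA may add KO-only regions near Maf, but the share did not leave the range of other windows. Wwox, a neighbour of Maf, had 5 WT-only and 11 KO-only regions among 106.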
